A study of Caenorhabditis elegans with 9 samples.

How the data were processed

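Poly(A) RNA of whole N2 worms was purified with oligo(dT) beads and sequenced, per the labels' protocols, which also give 50 µM S-adenosylmethionine from the L1 larval stage to the young adult in the same words for every sample. The labels do not say whether the F3 worms were themselves given SAM, and the series text mentions P. aeruginosa exposure while the RNA protocol describes no infected worms. Per the file headers, the authors deposited FPKM (fragments scaled by transcript length and library size) and estimated counts for 23807 genes and 32287 transcripts in 9 libraries. The labels name CASAVA 1.4 and the mouse builds mm9 and mm10, but the deposited chromosome identifiers were those of C. elegans WBcel235. The aligner and the counting tool are not given in the sources used here. Of the genes, 23802 matched the reference annotation by gene number, all on the same chromosome, and 22144 (93%) with the same start and end.

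The deposited estimated counts were checked against the FPKM values. Transcript counts under 500 all lay 0 to 1 above the product of FPKM, length and a constant per library, with a tolerance of 0.02, as for rounding up. Higher counts were not compared, and each of the 23807 gene counts was the sum of its transcripts. Counts of 4 and 8 were more frequent than their neighbours in all 9 libraries, so 4 counts may stand for 1 read pair. The library totals were 51298810 to 59201653 counts before division. Between replicates, the chi-square per degree of freedom of these divided counts was 11.3 to 139, so the spread between libraries was far above counting noise. Genes of ribosomal RNA held 2.13% to 5.02% of the counts, and the 10 most abundant genes 6.38% to 10.76%.

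Genes were tested if their FPKM was at least 1 in at least 3 of the 9 libraries, which left 13885. Estimated counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a mean per group over all 9 libraries and the quasi-likelihood test with robust priors. TMM factors ran from 0.748 in SAM_F3 2 to 1.176 in SAM_F3 3. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05. The comparisons were SAM_P0 against control_P0, SAM_F3 against control_P0 and SAM_F3 against SAM_P0. The comparisons, the filter, the gene lists, the rule for naming genes and most alternatives of the closing section were chosen before the data were examined. At that time the test was to be limma on log2 FPKM with a pseudocount of 1, and edgeR took its place once the tables proved to hold estimated counts. The limma test (version 3.58.1) is given as an alternative.

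Gene lists were tested with camera from limma, with a preset correlation of 0.01 between genes and, as an alternative, a correlation estimated from the data. The lists covered the methionine and SAM cycle, vitamin B12 and propionate, lipid synthesis, histone methylation, small RNA inheritance, immune signalling, P. aeruginosa response, DAF-16-linked stress genes, oxidative stress, heat shock and unfolded proteins, intracellular pathogen response, autophagy and lysosome, yolk proteins, oocyte and eggshell, early embryo, core germline, neurons, muscle and intestine. Families taken by name were cuticle collagens, moulting and hedgehog-related genes, sperm genes, C-type lectins, antimicrobial genes, cytochrome P450, glucuronosyltransferases and glutathione transferases, insulin-like peptides, neuropeptides, ribosomal proteins, histones, nuclear receptors and F-box genes. A list for proteins encoded in mitochondria matched 0 genes, which left 32 lists of at least 5 tested genes. Genes shared by lists counted in each.

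Genes were named by rule. For each comparison these were the 8 largest rises and the 8 largest falls among passing genes whose values did not overlap and whose higher mean was at least 5 FPKM, and the 2 passing members with the smallest adjusted p in each list. The genes sams-1, pmk-1, irg-4, irg-5, sysm-1, set-2, hrde-1 and vit-2 were named whatever their test. Genes passing in both comparisons against the controls were picked after their values were seen, as were further members of passing pairs.

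The pipeline was tested on simulated counts drawn from each gene's mean and dispersion and the real library sizes, with 59 to 71 genes changed at each fold among 13885. For SAM_P0 against control_P0, edgeR recovered 3% of the genes changed 1.5-fold, 14.1% of those changed 2-fold and 82.6% of those changed 4-fold, with 3 false calls. For SAM_F3 against control_P0 the shares were 0%, 15.3% and 80%, with 4 false calls, and for SAM_F3 against SAM_P0 they were 0% for 1.5-fold and 80.3% for 4-fold, with 3 false calls. By DESeq2 the 2-fold changes were recovered in 26.6%, 47.5% and 45.6%, with 27, 37 and 21 false calls. A simulated list of 30 genes raised 1.5-fold passed camera in each comparison, and an unchanged list of 30 did not. The genes were simulated independently and list members drawn at random, so this check did not cover lists of correlated genes.

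Alternatives on counts changed 1 choice each, except that the last left out 2 libraries. The pseudocount, quantile normalization and sums of transcript FPKM were run by limma on log2 FPKM, so they differ from the edgeR test in the test as well and are compared with limma at a pseudocount of 1. Those chosen in advance were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios, quantile and total-count scaling, the replicate number as a block, a fit to the groups compared alone, a prior without the mean trend, sums of transcript FPKM, at least a doubling or halving, and leaving out each library in turn. Chosen after seeing the data were DESeq2 1.42.0, the limma test, counts divided by 4, removal of ribosomal RNA genes, a prior without robust fitting, and leaving out SAM_F3 2 and control_P0 3 together. By deviations from group means, 0 libraries correlated best with their own number in both other groups. Of 9 same-number pairs 3 had r over 0.1, among them SAM_P0 3 with SAM_F3 3 (0.41) and SAM_P0 2 with SAM_F3 2 (0.33). SAM_P0 1 with SAM_F3 1 had -0.1. Pairing by replicate number was thus neither shown nor excluded. Scaling to library totals moved the median log2 fold of all genes in SAM_P0 against control_P0 from 0.02 to 0.13, and by limma quantile normalization moved it in SAM_F3 against control_P0 from 0.12 to -0.06 and in SAM_P0 against control_P0 from 0.10 to -0.02. The labels give no batch or date. No per-sample column of the tables was left out.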

Results

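RNA was sequenced from whole Caenorhabditis elegans worms of the N2 wild-type strain in 9 libraries, 3 in each of 3 groups. The groups were controls of the parental generation (control_P0), parental worms given 50 µM S-adenosylmethionine (SAM, the methyl donor of most methylation reactions; SAM_P0), and a group labelled with 50 µM SAM and generation 3 (SAM_F3). The deposited tables held estimated counts and FPKM for 23807 genes, and 13885 genes reached the FPKM minimum for testing. Library totals ran from 51298810 to 59201653 estimated counts. Values below are means ± SD of FPKM over n = 3 libraries per group, and log2 folds are given ± SE with a p adjusted over all genes tested. This SE was the absolute log2 fold divided by the square root of the quasi-likelihood F statistic, so it restates the test. The p-values measure only the spread between these libraries, since the labels do not say that the libraries came from separate cultures.

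The second principal component of log2 CPM (19.7% of the variance) separated the 3 groups, and library SAM_F3 2 lay apart from the others. On it control_P0 lay at 24.3 to 56.2, SAM_F3 at -16 to 1.1 and SAM_P0 at -43.9 to -30.5. By correlation the groups were not fully apart. Control_P0 3 correlated with SAM_F3 3 at 0.969, and with controls 1 and 2 at 0.979 and 0.967. The first principal component of log2 CPM held 54.9% of the variance, with SAM_F3 2 at 125.4, SAM_F3 1 and 3 at 32.7 and 36.3, control_P0 3 at 3.2, controls 1 and 2 at -20.7 and -41.3, and SAM_P0 between -49.1 and -41.7. Yolk genes had a median level of -2.12 (log2, relative to each gene's mean over the libraries) in SAM_F3 2, against 0.01 and -0.96 in SAM_F3 1 and 3. The germline list stood at -1.22 in SAM_F3 2 against -0.09 and -0.11. Control_P0 3 had more collagen mRNA than controls 1 and 2, with list medians of 0.16, -0.45 and -0.56, and less yolk mRNA, with 0.58, 2.03 and 1.19.

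**Figure D1:**
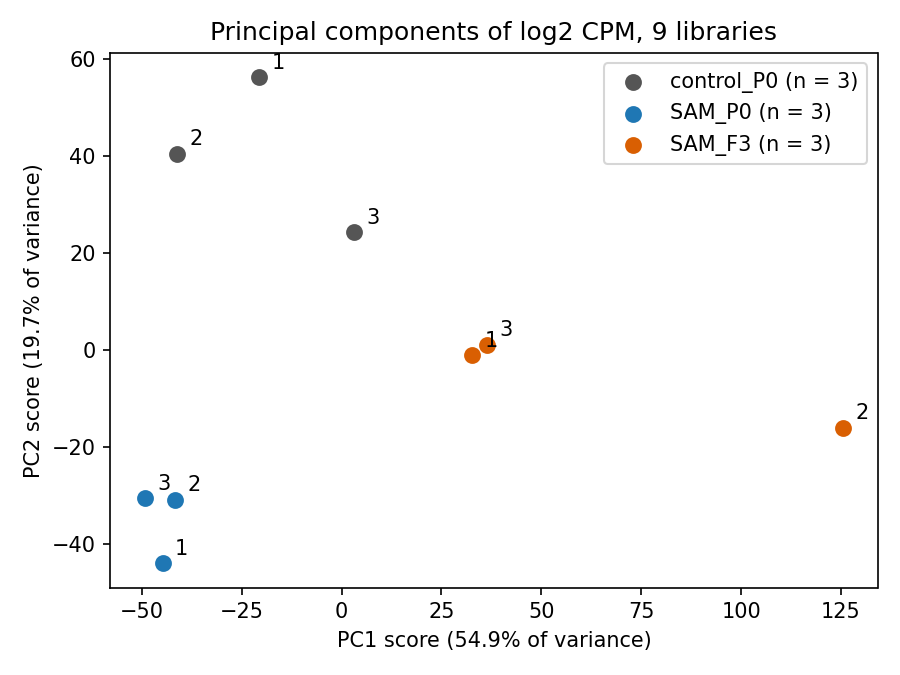
First against second principal component score of log2 CPM, one point per library, numbered by replicate and coloured by group (n = 3 each). SAM_F3 2 lies at 125.4 on the first component, and the 3 SAM_P0 libraries lie between -49.1 and -41.7.

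Worms given SAM had less mRNA of the pud genes, a lysosomal lipase and yolk proteins, and more of the small heat shock hsp-16 genes and of cuticle and moulting genes, than untreated worms of the same generation. The pud-4 gene, annotated as up-regulated at the protein level in an insulin receptor mutant (chromosome V, 2326678 to 2327282 on WBcel235), fell 25.8-fold (log2 -4.69 ± 0.31, adjusted p = 2e-04), from 169 ± 56.5 to 6.97 ± 0.128 FPKM. The lysosomal lipase gene lipl-1 (chromosome V, 12919986 to 12921692) fell 13.7-fold (log2 -3.78 ± 0.36, adjusted p = 0.0015), from 14.3 ± 5.57 to 1.11 ± 0.188 FPKM. The small heat shock gene hsp-16.1 (chromosome V, 9087293 to 9087782) rose 5.63-fold (log2 2.49 ± 0.24, adjusted p = 0.0015), from 22 ± 2.03 to 133 ± 31.1 FPKM. The yolk gene vit-2 (chromosome X, 5101042 to 5106169) fell 3.02-fold (log2 -1.59 ± 0.28, adjusted p = 0.014), from 1640 ± 365 to 583 ± 28.5 FPKM, but no longer passed without control_P0 1 or SAM_P0 1, 2 or 3 (adjusted p = 0.074, 0.092, 0.055 and 0.062). This comparison of SAM_P0 with control_P0 is the one in which generation was the same. Of 13885 genes, 617 passed (380 rose and 237 fell), 346 at least doubled and 218 at least halved. Values did not overlap between the groups for 4880 genes (35.1%), where chance gives 10%.

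Beside hsp-16.1, the uncharacterized gene W08E12.2 rose 21.6-fold (log2 4.44 ± 0.45), from 0.632 ± 0.299 to 15 ± 4.33 FPKM. The cuticle genes cut-2 and lon-3 rose 7.64-fold and 6.2-fold, and dod-21 rose by a log2 fold of 2.61 ± 0.51, from 135 ± 86.5 to 875 ± 154 FPKM. C32H11.9 and F57H12.6 rose 6.66-fold and 6.15-fold. Levels of C32H11.9 and the neighbouring dod-21 ran in parallel over the libraries, so the rises of this pair may not be separate. Without control_P0 3 the log2 folds of dod-21, C32H11.9, F57H12.6 and scl-12 were 3.26, 3.44, 3.37 and -3.49. The near-identical pairs F44E5.4 and F44E5.5 (8.27-fold and 8.41-fold) and hsp-16.1 and hsp-16.11 share sequence, so the split of reads within each pair is uncertain. Among the falls, pud-3 had a fold of 31.3 (log2 -4.97 ± 0.65), from 251 ± 13.3 to 8.63 ± 2.97 FPKM, and the near-identical pud-1.1 and pud-1.2 folds of 10.4 and 10.5. The gene pud-2.2 fell 8.98-fold, dod-3 18.2-fold and scl-12 17.4-fold, and F45D11.16 had a log2 fold of -3.65 ± 0.46. Control_P0 2 had only 6.75 FPKM of dod-3, against 70.1 and 61 in controls 1 and 3 and 2.23 to 3.37 in SAM_P0.

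Genes linked to the transcription factor DAF-16, which acts downstream of insulin signalling, were lower as a group. Of 29 tested, 0 rose and 12 fell (median log2 -1.16, camera adjusted p = 5.03e-16; adjusted p = 0.351 with an estimated correlation), and 19 fell when adjusted over the list alone. Among them lea-1 fell 3.41-fold and the linker histone gene hil-1 7.37-fold. Of 28 autophagy and lysosome genes, 0 rose and 2 fell, lipl-1 and lipl-2, and 11 fell when adjusted over the list alone (median log2 -0.43, camera adjusted p = 8.92e-07; 0.351 with an estimated correlation). Of 31 heat shock and unfolded protein genes, 8 rose and 0 fell, and 11 rose when adjusted over the list alone (median log2 0.25, camera adjusted p = 2.19e-07; 0.12 with an estimated correlation). The 8 rises included hsp-16.1, hsp-16.11, hsp-16.2, hsp-16.41, hsp-16.48 and hsp-16.49, so most of them came from the hsp-16 family. Beside hsp-16.1 and hsp-16.11, hsp-16.48 and hsp-16.49 had the same log2 fold (2.69), so these rises may not be separate. Without SAM_F3 2 and control_P0 3, 15 DAF-16-linked genes fell and 11 heat shock genes rose.

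Yolk and eggshell genes were lower while cuticle and moulting genes were higher. Of 6 yolk genes, 0 rose and 3 fell, and 6 fell when adjusted over the list alone (median log2 -1.60, camera adjusted p = 1.12e-06; 0.423 with an estimated correlation). Of 32 oocyte and eggshell genes, 0 rose and 2 fell, cav-1 (2.23-fold) and perm-4 (1.96-fold), with a median of -0.49 (camera adjusted p = 9.22e-06; 0.803 with an estimated correlation), and 3 fell when adjusted over the list alone. Without SAM_F3 2 and control_P0 3, 27 of the 32 fell. Of 155 cuticle collagen genes, 47 rose and 18 fell, and 78 rose and 37 fell when adjusted over the list alone (median log2 0.78, camera adjusted p = 5.5e-06; 0.803 with an estimated correlation). Of 75 moulting and hedgehog-related genes, 14 rose and 3 fell, and 34 rose and 9 fell when adjusted over the list alone (median log2 0.71, camera adjusted p = 6.91e-07; 0.623 with an estimated correlation). The moulting genes nas-36 and grl-15 rose 5.46-fold and 4.03-fold. Without control_P0 2 the collagen list no longer passed (median log2 0.75, camera adjusted p = 0.0745). Without control_P0 3, 28 moulting genes rose and 1 fell. The sperm list did not pass (0 of 85 rose or fell, median log2 -0.01, camera adjusted p = 0.632) but was higher without control_P0 2 (0.17, 0.00903).

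Immune and detoxification genes moved in both directions. The P. aeruginosa list held 34 genes known to be induced by the bacterium Pseudomonas aeruginosa or to need the kinase PMK-1. Of these, 5 rose and 3 fell, and 14 rose and 4 fell when adjusted over the list alone (median log2 0.44, camera adjusted p = 0.00296, and 0.623 with an estimated correlation). Among them irg-6 rose 4.69-fold, from 1.45 ± 0.257 to 7.31 ± 1.06 FPKM, and dod-17 rose 2.94-fold. The list also held dod-21, which is annotated as regulated by DAF-16, so it was not separate from DAF-16-linked genes. The genes irg-4, irg-5, sysm-1 and the kinase gene pmk-1 did not pass (adjusted p = 0.61, 0.48, 0.59 and 0.73), while without SAM_F3 2 irg-5 passed as lower (log2 -0.62, adjusted p = 0.014). Of 122 C-type lectin genes, 5 rose and 17 fell (median log2 -0.21, camera adjusted p = 0.00212; 0.623 with an estimated correlation), with clec-174 up 4.98-fold and clec-222 down 4.99-fold; adjusted over the list alone, 16 rose and 29 fell, and the median was -0.14 without control_P0 3. Of 77 antimicrobial genes, 7 rose and 8 fell, and 10 rose and 10 fell when adjusted over the list alone (camera adjusted p = 0.17); spp-2 fell 3.54-fold and thn-2 4.8-fold. Of 40 cytochrome P450 genes, 0 rose and 7 fell, and 13 fell when adjusted over the list alone (median log2 -0.23, camera adjusted p = 0.00043; 0.623 with an estimated correlation). Of 79 genes of the glucuronosyltransferase and glutathione transferase families, 9 rose and 1 fell, and 22 rose and 3 fell when adjusted over the list alone (median log2 0.28, camera adjusted p = 0.00128; 0.351 with an estimated correlation).

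In the methionine and SAM cycle, 0 of 27 genes rose and 2 fell, the SAM synthetase gene sams-5 (1.91-fold, from 20.2 ± 4.32 FPKM) and the methyltransferase gene comt-4 (3.46-fold; log2 -1.79, and -1.1 without control_P0 2, where it no longer passed), with a camera adjusted p of 0.836; adjusted over the list alone, 1 rose and 2 fell. The gene sams-1 did not pass, at 71.7 ± 27.5 in controls and 118 ± 3 in SAM_P0 (adjusted p = 0.26). Of 42 histone methylation genes, 1 rose, set-30 (2.83-fold), and 0 fell (camera adjusted p = 0.366), and set-2 did not pass (adjusted p = 0.97). Of 54 small RNA genes, 0 rose and 0 fell by edgeR (camera adjusted p = 0.304), and hrde-1 did not pass (adjusted p = 0.91). In lipid synthesis, 1 of 28 genes rose, ckb-2, and 1 fell, the desaturase gene fat-7 (3.82-fold), and 2 rose and 9 fell when adjusted over the list alone (median log2 -0.40, camera adjusted p = 0.0074; 0.623 with an estimated correlation).

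The other lists that passed were all lower in SAM_P0. They were intestine (5 of 24 fell; camera adjusted p = 0.00152), intracellular pathogen response (1 of 17 fell; 0.00085), neuropeptides (1 of 73 fell; 0.00135), immune signalling (1 of 42 rose; 0.0461) and nuclear receptors (2 of 162 fell; 0.0379). With an estimated correlation the adjusted p of the 5 lists was 0.623, 0.623, 0.848, 0.837 and 0.919. Adjusted over the list alone, 5 intestine genes fell and 1 rose, 3 intracellular pathogen genes fell and 1 rose, and 0 passed in the other 3 lists. Without control_P0 3 the medians of the intracellular pathogen and neuropeptide lists moved from -0.91 and -0.28 to -0.51 and -0.15, and the immune signalling and nuclear receptor lists no longer passed (0.266 and 0.35). The immune signalling list also failed without SAM_P0 3 or SAM_F3 1 (0.101 and 0.0595), and the nuclear receptor list without SAM_P0 2 (0.204), while its median was -0.26 without control_P0 2. Without SAM_F3 2 and control_P0 3 the intracellular pathogen, immune signalling and nuclear receptor lists no longer passed (camera adjusted p = 0.067, 0.261 and 0.357). The lists for vitamin B12 and propionate, oxidative stress, early embryo, core germline, neurons, muscle, insulin-like peptides, ribosomal proteins, histones and F-box genes did not pass (camera adjusted p = 0.565, 0.878, 0.551, 0.468, 0.465, 0.657, 0.0526, 0.0702, 0.0735 and 0.632). The ribosomal list passed as lower without control_P0 3, SAM_P0 2, SAM_F3 2 or SAM_F3 3 (0.00794, 0.00681, 0.0206 and 0.0469), the insulin-like list without control_P0 1 or SAM_P0 2 (0.033 and 0.016), and histones without control_P0 2 or SAM_P0 2 (0.0251 and 0.0457). In all, 17 of 32 lists passed with the preset correlation and 0 with an estimated one. The number of genes passing depended on single libraries, with 64 (28 rose and 36 fell), 376 (131 rose and 245 fell) and 669 (522 rose and 147 fell) without control_P0 1, 2 and 3, 77, 189 and 232 without SAM_P0 1, 2 and 3, and 2123 without SAM_F3 2. A fit to these groups alone called 2063 genes and DESeq2 called 1482, and both kept the calls of all 57 named genes, while 24 of the 57 passed without control_P0 1. By limma on log2 FPKM the share of rises was 73.2%, and 61.1% once quantile normalization was added.

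**Figure D2:**
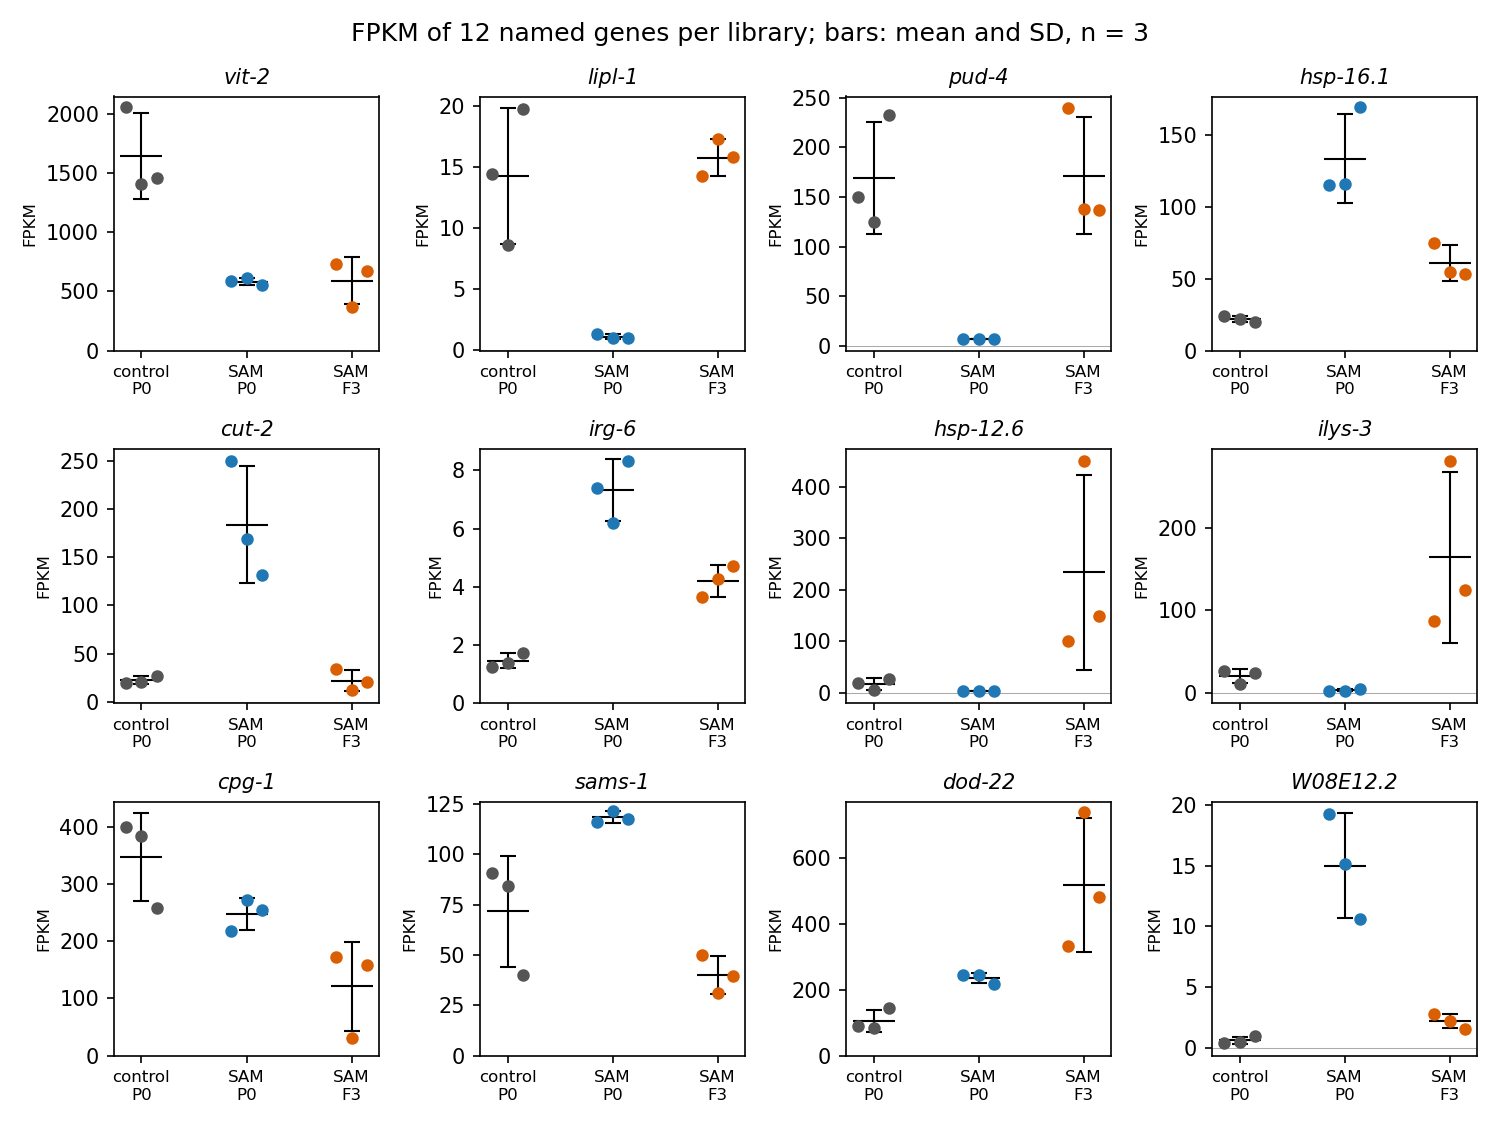
FPKM of 12 named genes per library, one point per library, with bars for the mean and SD of each group (n = 3). The yolk gene vit-2 had 1640 ± 365 FPKM in control_P0, 583 ± 28.5 in SAM_P0 and 592 ± 198 in SAM_F3, and pud-4 fell to 6.97 ± 0.128 in SAM_P0 alone.

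Worms of SAM_F3 had less mRNA of yolk, eggshell, sperm and germline genes, and more of antimicrobial, F-box and neuropeptide genes, than the parental controls. The gene vit-2 fell 3.01-fold (log2 -1.59 ± 0.28, adjusted p = 0.02), from 1640 ± 365 to 592 ± 198 FPKM. It no longer passed without control_P0 1 or 2 (adjusted p = 0.068 and 0.087). The eggshell gene cpg-1 (chromosome III, 4489359 to 4491392) fell 3.26-fold (log2 -1.70 ± 0.43, adjusted p = 0.026), from 347 ± 77.4 to 121 ± 77.5 FPKM. The small heat shock gene hsp-12.6 (chromosome IV, 9446229 to 9447228) rose 14.6-fold (log2 3.87 ± 0.73, adjusted p = 0.02), from 17.1 ± 10.8 to 234 ± 190 FPKM. SAM_F3 2 held 451 FPKM of it, against 101 and 149 in SAM_F3 1 and 3, and without SAM_F3 2 its log2 fold was 2.65. The saposin-like gene spp-13 rose 6.12-fold (log2 2.61 ± 0.45, adjusted p = 0.02), from 6.45 ± 3.52 to 38.9 ± 13.8 FPKM. This comparison of SAM_F3 with control_P0 addresses what remained in descendants, but the series has 0 untreated F3 libraries, so treatment, generation and batch cannot be separated. Of 13885 genes, 2937 passed (1846 rose and 1091 fell), 1454 at least doubled and 422 at least halved. Values did not overlap for 4999 genes (36%), where chance gives 10%, and the smallest adjusted p was 0.016.

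Rises were ranked by mean log2 FPKM with a pseudocount of 1. Among passing genes without overlap and with a mean of at least 5 FPKM in SAM_F3, the 8 largest rises were in R10D12.6 (45.6-fold), T20D4.12 (21.9-fold), T28A11.19 (20.7-fold), the protease gene cpr-2 (18.9-fold), the near-identical C32H11.11 and C32H11.8 (15.3-fold and 14.9-fold), hsp-12.6 and K03D3.2 (log2 3.63 ± 0.74). Without SAM_F3 2 the log2 folds of R10D12.6, T20D4.12, T28A11.19 and K03D3.2 were 4.11, 3.61, 3.18 and 2.69, against 5.51, 4.45, 4.37 and 3.63 with it. Control_P0 2 had 0 FPKM of R10D12.6, and without control_P0 3 the log2 folds of R10D12.6 and T20D4.12 were 7.21 and 5.45. Falls beside vit-2 and cpg-1 included vit-5 (3.86-fold), the near-identical vit-3 and vit-4 (5.66-fold and 5.95-fold), K08D12.6 (4.01-fold), the germline stem cell gene sygl-1 (3.46-fold), C39D10.7 (3.33-fold) and C06A1.12 (3.17-fold). Without SAM_F3 1 the log2 folds of vit-3 and vit-4 were -3.41 and -3.57, against -2.50 and -2.57 with it, and without control_P0 1 vit-4 had -1.97 and no longer passed. In SAM_F3 2 cpg-1 stood at 31.5 FPKM, against 172 and 159 in SAM_F3 1 and 3.

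Oocyte, sperm, yolk and core germline lists were lower in SAM_F3. Of 32 oocyte and eggshell genes, 0 rose and 24 fell, and 26 fell when adjusted over the list alone (median log2 -1.25, camera adjusted p = 6.67e-15; 0.805 with an estimated correlation). Of 85 sperm genes, 1 rose and 40 fell, and 47 fell when adjusted over the list alone (median log2 -0.75, camera adjusted p = 2.12e-14; 0.805 with an estimated correlation). Of 6 yolk genes, 0 rose and 6 fell, over the list alone as over all genes (median log2 -2.09, camera adjusted p = 3.61e-07; 0.62 with an estimated correlation). Of 30 core germline genes, 0 rose and 8 fell, among them daz-1 (2.6-fold) and rnp-8 (2.56-fold), and 14 fell when adjusted over the list alone (median log2 -0.50, camera adjusted p = 2.29e-05; 0.806 with an estimated correlation). Without SAM_F3 2, 24 oocyte genes, 41 sperm genes, 5 yolk genes and 11 core germline genes fell, with medians of -0.92, -0.70, -1.69 and -0.30. The sperm genes ssp-10 and gsp-4 fell 2.64-fold and 2.22-fold.

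Small RNA and histone methylation genes were lower as lists, as were oocyte and core germline genes (median log2 -1.25 and -0.50). Whether small RNA and histone methylation genes fell beyond a lower share of germline RNA was not tested. Of 54 small RNA genes, 1 rose and 11 fell, the same counts as when adjusted over the list alone (median log2 -0.42, camera adjusted p = 3.29e-06; 0.806 with an estimated correlation). Among them the Argonaute genes alg-3 and alg-4, which act in spermatogenesis, fell 2.24-fold and 2.07-fold. The nuclear Argonaute gene hrde-1 did not pass, at 65.5 ± 13 in controls and 33.2 ± 21.1 in SAM_F3 (log2 -1.16, adjusted p = 0.062), but passed as lower without SAM_F3 1 or 2 (log2 -1.50 and -0.74, adjusted p = 0.04 and 0.021). Without SAM_F3 2, in which the oocyte and germline lists also lay lowest, the median of the small RNA list and that of the histone methylation list were both -0.25 (camera adjusted p = 0.00437 and 0.0236). Of 42 histone methylation genes, 2 rose and 3 fell, among them set-9 (2.48-fold) and set-17 (1.56-fold), and 0 passed when adjusted over the list alone (median log2 -0.42, camera adjusted p = 0.00139; 0.806 with an estimated correlation). The methyltransferase gene set-2 did not pass (adjusted p = 0.16). In the methionine and SAM cycle, 1 of 27 genes rose and 5 fell, and 10 fell when adjusted over the list alone (median log2 -0.29, camera adjusted p = 0.0528; 0.00574, 0.0412 and 0.0083 without control_P0 3, SAM_F3 1 and SAM_F3 2). Among them ahcy-1, which clears the product of methylation, fell 1.95-fold from 493 ± 109 to 269 ± 68.7 FPKM, sams-1 fell 1.9-fold and mthf-1 1.66-fold. The call of sams-1 was lost on leaving out any library but control_P0 3 or SAM_F3 1 (adjusted p = 0.058 to 0.17). In the vitamin B12 list 1 of 15 rose, mce-1 (1.5-fold), and 1 fell, metr-1 (1.7-fold; camera adjusted p = 0.417).

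Antimicrobial, F-box, neuropeptide, nuclear receptor and detoxification lists were higher. The neuron, muscle, intestine and collagen lists did not pass, with median log2 folds of 0.45, 0.14, 0.27 and 0.02. Whether a lower share of germline RNA contributed to the rises was not tested. Of 77 antimicrobial genes, 33 rose and 0 fell, and 42 rose when adjusted over the list alone (median log2 0.89, camera adjusted p = 7.01e-09; 0.806 with an estimated correlation), among them cnc-3 (5.48-fold). Of 132 F-box genes, 41 rose and 2 fell, and 50 rose and 2 fell when adjusted over the list alone (median log2 0.75, camera adjusted p = 3.21e-07; 0.62 with an estimated correlation). Of 73 neuropeptide genes, 20 rose and 0 fell, over the list alone as over all genes (median log2 0.61, camera adjusted p = 0.000201; 0.833 with an estimated correlation), among them flp-1 (2.48-fold) and nlp-50 (5.23-fold; log2 2.39, and 1.56 without SAM_F3 2). Without SAM_F3 2, 29 antimicrobial genes rose, 46 F-box genes rose, and 17 neuropeptide genes rose and 3 fell, and the medians of the antimicrobial, neuropeptide and nuclear receptor lists were 0.72, 0.32 and 0.37. Of 162 nuclear receptor genes, 22 rose and 0 fell, and 6 rose when adjusted over the list alone (median log2 0.57, camera adjusted p = 0.000355; 0.806 with an estimated correlation). Of 40 cytochrome P450 genes, 11 rose and 0 fell, and 15 rose when adjusted over the list alone (median log2 0.66, camera adjusted p = 0.00139; 0.806 with an estimated correlation). Of 79 glucuronosyltransferase and glutathione transferase genes, 13 rose and 0 fell, and 12 rose when adjusted over the list alone (median log2 0.39, camera adjusted p = 0.00418; 0.62 with an estimated correlation).

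In the P. aeruginosa list, 7 of 34 genes rose and 2 fell, and 7 rose and 3 fell when adjusted over the list alone (median log2 0.52, camera adjusted p = 0.0843). The gene dod-22 rose 5.03-fold, from 105 ± 33.8 to 519 ± 205 FPKM, irg-6 rose 2.81-fold and sysm-1 fell 3.19-fold, which no longer passed without control_P0 1, control_P0 2 or SAM_P0 1 (adjusted p = 0.13, 0.098 and 0.05). The genes pmk-1, irg-4 and irg-5 did not pass (adjusted p = 0.67, 0.12 and 0.6), but irg-4 passed as higher without SAM_F3 1 (log2 0.79, adjusted p = 0.03) and irg-5 as lower without SAM_F3 2 (log2 -0.50, adjusted p = 0.042). The P. aeruginosa list passed as higher without SAM_F3 1 (0.0347), and the lectin list without control_P0 3 or SAM_F3 1 (0.0316 and 0.0378). C-type lectins did not pass as a list (22 of 122 rose and 8 fell; camera adjusted p = 0.0843), and clec-70 rose 5.3-fold. The insulin-like genes ins-11 and ins-33 rose 8.27-fold and 6.36-fold in a list of 24 of which 7 rose and 3 fell (camera adjusted p = 0.387). Without SAM_F3 2 the log2 folds of ins-11 and ins-33 were 2.26 and 1.79, against 3.05 and 2.67 with it. The moulting list (11 of 75 rose and 1 fell; camera adjusted p = 0.024; 0.838 with an estimated correlation) and the intracellular pathogen list (3 of 17 rose; 0.0255; 0.806 with an estimated correlation) passed. Under scaling to library totals both lists no longer passed, with adjusted p = 0.0625 and 0.0666, and without SAM_F3 2 the moulting list had 0.0676. The moulting list also failed without control_P0 2 (median log2 0.19, adjusted p = 0.239) and had a median of 0.81 without control_P0 3, and the intracellular pathogen list failed without control_P0 1 or SAM_F3 3 (0.0956 and 0.259).

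The lists for cuticle collagens (13 of 155 rose and 23 fell), DAF-16-linked genes (4 of 29 rose and 1 fell), heat shock genes (8 of 31 rose and 3 fell), immune signalling (5 of 42 rose and 5 fell) and muscle (1 of 31 rose and 5 fell) did not pass (camera adjusted p = 0.0984, 0.183, 0.572, 0.926 and 0.264). The collagen list was lower without control_P0 1 or 2 (0.0355 and 0.00443), and the DAF-16-linked list higher without SAM_F3 1 (0.0347). Without SAM_F3 2 the collagen list was lower (median log2 -0.32, camera adjusted p = 1.53e-05), as were the lipid synthesis list (-0.21, 0.014), histones (-0.14, 0.0393), the ribosomal list (-0.36, 1.97e-07) and the muscle list (-0.25, 0.00127). The lists for lipid synthesis, oxidative stress, autophagy, early embryo, neurons, intestine, ribosomal proteins and histones did not pass (camera adjusted p = 0.16, 0.49, 0.756, 0.571, 0.299, 0.571, 0.264 and 0.571). In all, 14 of 32 lists passed with the preset correlation and 0 with an estimated one. The calls of single genes in SAM_F3 against control_P0 rested on the spread shared across groups. By edgeR, a fit to these groups alone called 0 genes (4159 at an unadjusted p under 0.05), leaving out control_P0 1 gave 0 (3810 unadjusted) and leaving out control_P0 2 gave 3 (3925 unadjusted), against 4221 by DESeq2 and 2646 by limma on all libraries. Without SAM_P0 1, 2 or 3 the counts were 1557, 1761 and 1700. Scaling to library totals gave 1768 rises and 251 falls by edgeR. By limma on log2 FPKM there were 2217 rises and 429 falls, and 1594 rises and 1877 falls once quantile normalization was added.

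**Figure D3:**
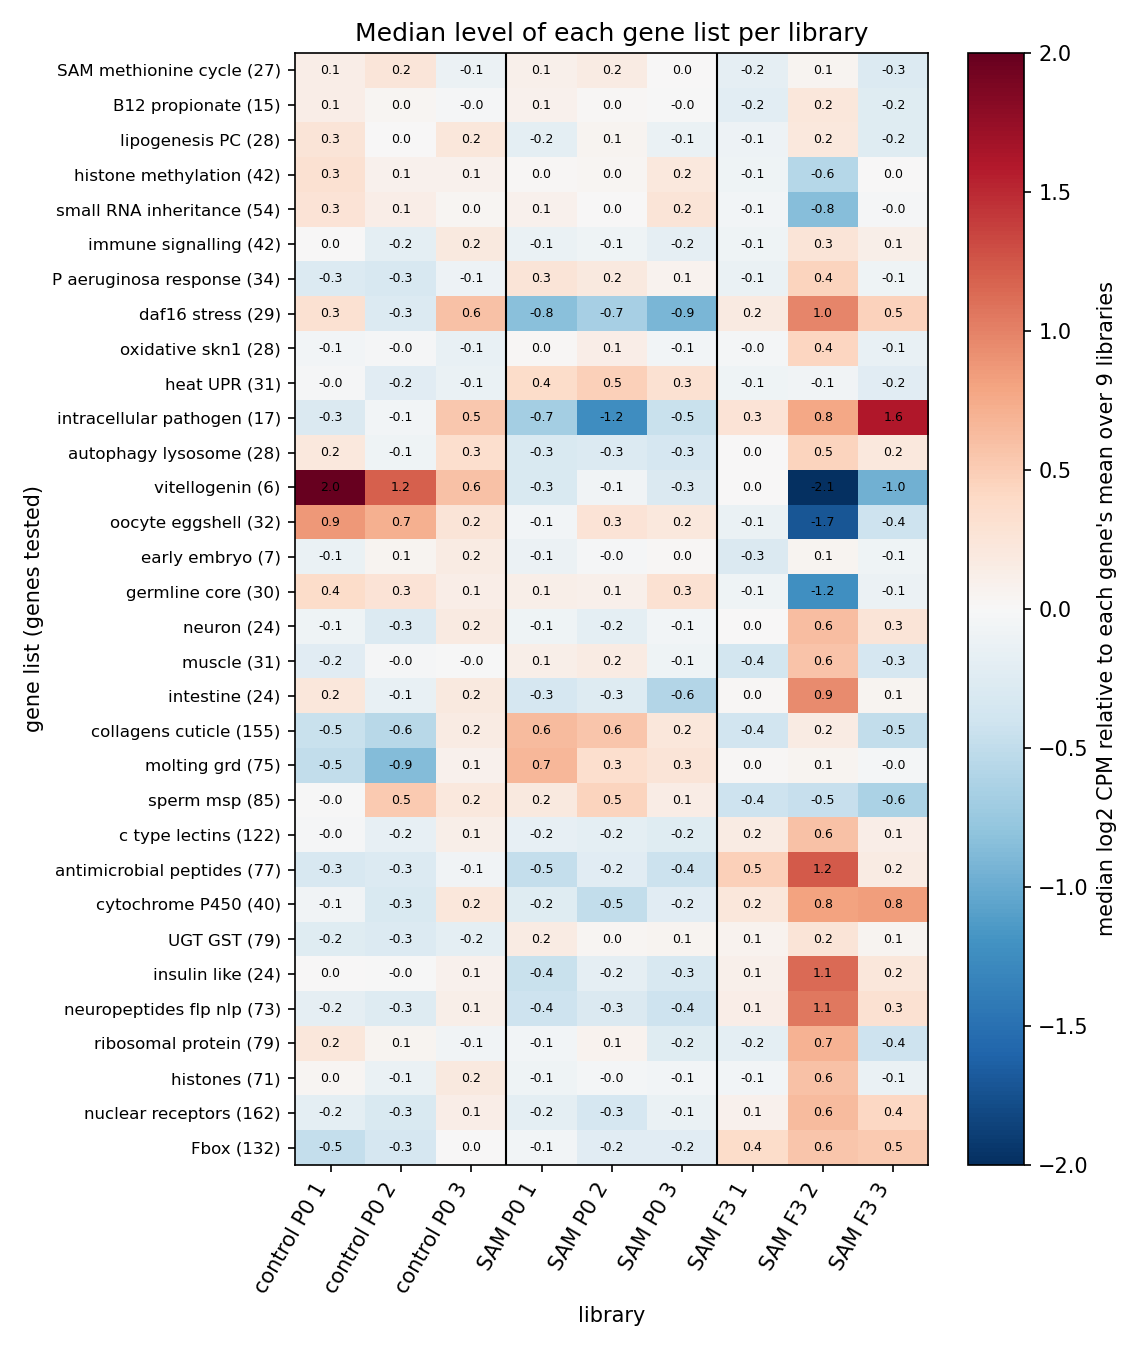
Median log2 CPM of each gene list in each of the 9 libraries, relative to each gene's mean over the libraries, with the number of genes tested in brackets. SAM_F3 2 holds the lowest oocyte value, -1.71, and the 3 SAM_P0 libraries hold the lowest DAF-16 values, -0.66 to -0.91.

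Compared with SAM_P0, SAM_F3 had far more mRNA of DAF-16-linked genes, a lysozyme and a lipase, and less of cuticle, sperm and some small heat shock hsp-16 genes. Other hsp-16 genes were not lower. Against the controls, hsp-16.48 and hsp-16.49 both had a log2 fold of 2.69 in SAM_P0, and 2.7 and 2.71 in SAM_F3. The gene hsp-12.6 rose 94.8-fold (log2 6.57 ± 0.84, adjusted p = 0.0018), from 2.82 ± 0.233 to 234 ± 190 FPKM, with a log2 fold of 5.36 without SAM_F3 2. The lysozyme gene ilys-3 (chromosome IV, 2464456 to 2465443) rose 72.2-fold (log2 6.17 ± 0.69, adjusted p = 0.0014), from 2.56 ± 1.28 FPKM to 86.6, 283 and 125 FPKM in SAM_F3 1, 2 and 3, and its log2 fold was 5.27 without SAM_F3 2. The gene lipl-1 rose 14.8-fold (log2 3.89 ± 0.36, adjusted p = 0.0014), from 1.11 ± 0.188 to 15.8 ± 1.5 FPKM, beside 14.3 ± 5.57 in the controls. The gene cut-2 fell 8.39-fold (log2 -3.07 ± 0.34, adjusted p = 0.0014), from 184 ± 60.5 to 22.3 ± 11.3 FPKM. The SAM synthetase gene sams-1 fell 2.92-fold (log2 -1.55 ± 0.29, adjusted p = 0.0061), from 118 ± 3 to 40.2 ± 9.43 FPKM. In this comparison both groups carried the SAM label and generation differed. Of 13885 genes, 2869 passed (1916 rose and 953 fell), 1659 at least doubled and 463 at least halved. Values did not overlap for 6038 genes (43.5%), where chance gives 10%.

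The noncoding RNA tts-1 rose 64.4-fold, from 210 ± 26.4 to 11800 ± 9110 FPKM, and took 1.706% of all counts in SAM_F3 2 against 0.455% and 0.649% in SAM_F3 1 and 3; without stated strand its counts may hold those of overlapping genes. The metallothionein gene mtl-1 rose 50.3-fold, scl-12 62.9-fold and scl-13 66.9-fold, and the near-identical Y75B12B.8 and C41G6.13 rose 74.8-fold and 73.1-fold. Without SAM_F3 2 the log2 folds of tts-1, scl-13, Y75B12B.8 and C41G6.13 were 4.87, 5.37, 5.38 and 5.38, against 6.01, 6.06, 6.23 and 6.19 with it. Falls included C32H11.9 (7.4-fold), dod-21 (7.26-fold), W08E12.2 (6.53-fold), F22E5.1 (6.51-fold), K11H12.4 (5.34-fold), col-126 (5.07-fold) and col-127 (4.99-fold). Levels of C32H11.9 and dod-21 ran in parallel over the libraries, as did those of col-126 and col-127, so the falls within each pair may not be separate.

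DAF-16-linked, lysosomal and intestine lists were higher in SAM_F3 than in SAM_P0, and the heat shock list was lower. Of 29 DAF-16-linked genes, 19 rose and 0 fell, and 20 rose when adjusted over the list alone (median log2 1.33, camera adjusted p = 1.4e-11; 0.559 with an estimated correlation), among them hsp-12.3 (19.5-fold). Of 28 autophagy and lysosome genes, 10 rose and 0 fell, and 11 rose when adjusted over the list alone (median log2 0.52, camera adjusted p = 9.49e-05; 0.573 with an estimated correlation). Of 24 intestine genes, 7 rose and 0 fell, among them cpr-1 (8.9-fold, 203 ± 13.1 to 1660 ± 753 FPKM) and cpr-4 (6.01-fold), and 12 rose and 1 fell when adjusted over the list alone (median log2 0.80, camera adjusted p = 0.00352; 0.68 with an estimated correlation). Of 31 heat shock genes, 1 rose and 12 fell, among them hsp-4 (2.36-fold) and hsp-16.11 (2.14-fold), and 4 rose and 14 fell when adjusted over the list alone (median log2 -0.41, camera adjusted p = 0.000593; 0.559 with an estimated correlation). Without SAM_F3 2, 19 DAF-16-linked genes rose and 13 heat shock genes fell, and the log2 folds of hsp-12.3 and cpr-1 were 3.64 and 2.5, against 4.28 and 3.15 with it. The medians of the lysosome and intestine lists were then 0.32 and 0.41.

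Antimicrobial, lectin, intracellular pathogen, neuropeptide, cytochrome P450, F-box and nuclear receptor lists were higher. As against the controls, a contribution of a lower share of germline RNA was not tested. Of 77 antimicrobial genes, 39 rose and 4 fell, and 42 rose and 6 fell when adjusted over the list alone (median log2 0.97, camera adjusted p = 4.43e-10; 0.574 with an estimated correlation), and the median was 0.63 without SAM_F3 2; spp-2 rose 5.82-fold. Of 122 C-type lectins, 41 rose and 9 fell, among the rises clec-222 (10.7-fold) and clec-169 (10.6-fold), and 49 rose and 13 fell when adjusted over the list alone (median log2 0.43, camera adjusted p = 0.000166; 0.574 with an estimated correlation). Of 17 intracellular pathogen genes, 11 rose and 0 fell, and 14 rose when adjusted over the list alone (median log2 1.81, camera adjusted p = 3.88e-06; 0.574 with an estimated correlation), among them skr-5 (4.49-fold) and pals-39 (4.47-fold). Of 73 neuropeptide genes, 32 rose and 0 fell, and 44 rose when adjusted over the list alone (median log2 0.91, camera adjusted p = 2.13e-09; 0.68 with an estimated correlation). Of 40 cytochrome P450 genes, 20 rose and 1 fell, over the list alone as over all genes (mean log2 1.16, camera adjusted p = 3.83e-08; 0.559 with an estimated correlation), among them cyp-37B1 (13.9-fold) and cyp-13A5 (10.5-fold). Of 132 F-box genes, 42 rose and 1 fell, and 51 rose and 1 fell when adjusted over the list alone (median log2 0.66, camera adjusted p = 3.51e-07; 0.559 with an estimated correlation). Of 162 nuclear receptor genes, 39 rose and 0 fell, and 50 rose when adjusted over the list alone (median log2 0.55, camera adjusted p = 4.26e-07; 0.68 with an estimated correlation). Genes of the P. aeruginosa list moved both ways (6 of 34 rose and 7 fell, camera adjusted p = 0.61), and dod-17 fell 3.18-fold.

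Collagen, sperm, oocyte and core germline lists were lower. Of 155 collagen genes, 28 rose and 61 fell, and 32 rose and 72 fell when adjusted over the list alone (median log2 -0.62, camera adjusted p = 3.7e-07; 0.68 with an estimated correlation), while col-108 rose 71.3-fold (log2 6.16, and 5.39 without SAM_F3 2). Of 85 sperm genes, 0 rose and 42 fell, and 47 fell when adjusted over the list alone (median log2 -0.77, camera adjusted p = 2.79e-13; 0.574 with an estimated correlation). Oocyte genes (1 of 32 rose and 1 fell; camera adjusted p = 9.49e-05) and core germline genes (3 of 30 fell; 0.000844) were lower as lists, with medians of -0.76 and -0.49, which were -0.37 and -0.14 without SAM_F3 2, and both had 0.68 with an estimated correlation. Small RNA (median log2 -0.34, camera adjusted p = 0.000608) and histone methylation genes (-0.33; 0.0302) were lower as lists but no longer passed without SAM_F3 2 (camera adjusted p = 0.075 and 0.2), and had 0.68 and 0.712 with an estimated correlation. Without SAM_P0 3 the histone methylation list failed (0.0902) and the small RNA list had a median of -0.21. Whether these lists fell beyond a lower share of germline RNA was not tested here either. The demethylase gene nmad-1 rose 4.14-fold. Insulin-like genes passed (10 of 24 rose and 2 fell; camera adjusted p = 0.0167) but had 0.0511 without SAM_F3 2 and 0.68 with an estimated correlation, with ins-11 up 13.6-fold (log2 3.77, and 2.99 without SAM_F3 2) and daf-28 down 6.69-fold. Yolk genes did not pass (0 of 6 rose or fell by edgeR; camera adjusted p = 0.246) but were lower without SAM_F3 1 (median log2 -1.22, 0.0239), and vit-2 had a log2 fold of 0.00 ± 0.27. The genes irg-4, irg-5, pmk-1, sysm-1, set-2 and hrde-1 did not pass (adjusted p = 0.41, 0.13, 0.9, 0.087, 0.19 and 0.09), but irg-5 passed as higher without SAM_F3 3 (0.039), sysm-1 as lower without control_P0 3 (0.049) and hrde-1 as lower without SAM_F3 2 (0.049).

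In the methionine and SAM cycle, 3 of 27 genes rose and 6 fell, among the falls sams-1 and cbs-1 (1.94-fold), with a camera adjusted p of 0.102 that was 0.0224 without SAM_F3 2. In lipid synthesis, 7 of 28 genes rose and 3 fell (camera adjusted p = 0.624), with the desaturase genes fat-3 and fat-2 up 3.54-fold and 2.88-fold. The lists for moulting, glucuronosyltransferases and glutathione transferases, immune signalling, vitamin B12, oxidative stress, early embryo, neurons, muscle, ribosomal proteins and histones did not pass (camera adjusted p = 0.119, 0.806, 0.151, 0.792, 0.61, 0.967, 0.102, 0.151, 0.806 and 0.512), while without SAM_F3 2 muscle was lower (-0.35, 8.03e-05), without SAM_F3 1 neurons were higher (0.0436) and without SAM_P0 3 moulting genes lower (0.0187). The oxidative stress gene ftn-1 rose 14.6-fold and the histone gene hil-1 rose 26-fold (log2 4.70, and 3.92 without SAM_F3 2). In all, 18 of 32 lists passed with the preset correlation and 0 with an estimated one. Without SAM_P0 1, 2 or 3 the number of genes called was 989, 1124 and 1198, and 62 to 63 of the 72 named genes stayed called in each. By limma on log2 FPKM the share of rises was 71.7%, and 51.3% once quantile normalization was added.

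Genes that rose in SAM_P0 lay partly higher in SAM_F3 too, whereas genes that fell in SAM_P0 mostly did not. Of the 380 genes that rose in SAM_P0, 311 (81.8%) had a higher mean in SAM_F3 than in control_P0 and 138 passed there, with a median log2 fold of 1.49 in SAM_P0 and 0.64 in SAM_F3. The 138 included hsp-16.1 (2.65-fold in SAM_F3), irg-6 (2.81-fold), spp-13 and cnc-3. Of the 237 genes that fell in SAM_P0, 61 (25.7%) lay lower in SAM_F3 than in control_P0 and 15 passed there, among them vit-2, vit-6 and perm-4, with a median log2 fold of -2.18 in SAM_P0 and 0.56 in SAM_F3. Of these 237 genes, 211 passed as higher in SAM_F3 than in SAM_P0, and 170 of the 380 rises passed as lower, although these genes had been chosen on the same SAM_P0 libraries. Independent lists of these sizes would share 50.52 rises and 18.62 falls; 4 genes rose in SAM_P0 and fell in SAM_F3 (29.86 for independent lists) and 35 fell and then rose (31.51).

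Both comparisons used the same 3 control libraries, which cannot be split, so part of the excess of shared rises may come from the controls. Across 13885 genes, which are not independent replicates, the log2 folds had Pearson r = 0.11 by edgeR. The jackknife SE of r over the 9 libraries was 0.221, larger than r itself. Leaving out 1 library gave r of 0.051 (without control_P0 1) to 0.306 (without control_P0 3). Without SAM_F3 2 and control_P0 3, a removal chosen after the results were seen, r was 0.403. The differences of mean log2 CPM had a covariance of 0.0905 and r = 0.1625. In 988 simulated sets of unchanged groups the mean covariance was 0.0729 (-0.0400 to 0.339) and the mean r 0.441 (-0.487 to 0.956). Every simulated group, the shared control included, was drawn from the deviations of all 9 libraries, SAM_F3 2 among them. These values are therefore not those of the 3 control libraries and cannot show how much the controls contributed.

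**Figure D4:**
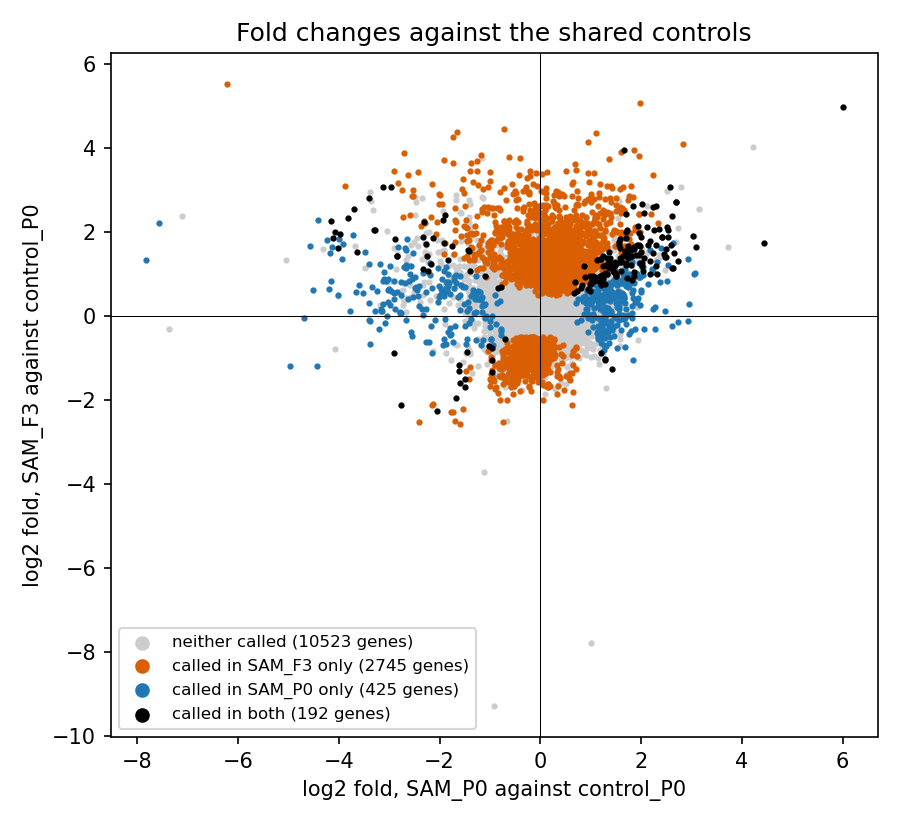
Log2 fold of each tested gene in SAM_P0 (x axis) and in SAM_F3 (y axis) against the shared control_P0 libraries, one point per gene, coloured by where the gene passed. A total of 192 genes passed in both comparisons, 425 in SAM_P0 alone and 2745 in SAM_F3 alone.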

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

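DESeq2, limma, division by 4, robustness of the prior, removal of ribosomal RNA genes and the joint removal of SAM_F3 2 and control_P0 3 were chosen after the results were seen. Of the 57, 76 and 72 named genes that passed in SAM_P0 against control_P0, SAM_F3 against control_P0 and SAM_F3 against SAM_P0, 0 reversed in any alternative, and DESeq2 kept the calls of all of them. These genes were chosen on the same libraries, so few reversals could arise. Calls were lost, however. Of the 76, 0 kept their call in the fit to the 2 groups alone and without control_P0 1, and 3 without control_P0 2. With an estimated correlation 0 gene lists passed in each comparison. For SAM_P0 against control_P0 the 617 genes became 383 at a mean FPKM of at least 5, where fewer genes were tested, 2063 in the fit to the 2 groups alone, 1482 by DESeq2 and 2572 without SAM_F3 2 and control_P0 3. For SAM_F3 against control_P0 the 2937 became 1876 for at least a doubling or halving, 0 by edgeR in the fit to the 2 groups alone (4159 at an unadjusted p under 0.05; 4221 by DESeq2 on all libraries), and 4680 without SAM_F3 2 and control_P0 3. Leaving out 1 library gave 64 (without control_P0 1) to 2123 (without SAM_F3 2), 0 (without control_P0 1; 3810 unadjusted) to 3258 (without SAM_F3 2), and 989 (without SAM_P0 1) to 3190 (without SAM_F3 3) genes for the 3 comparisons. SAM_F3 2 thus widened the shared spread in SAM_P0 against control_P0, a comparison that does not contain it. With the replicate block the counts were 432, 2190 and 2426. The correlation of 0.11 between both sets of folds against the controls was 0.403 without a filter and 0.403 without SAM_F3 2 and control_P0 3, and the cause was not tested. The log2 fold of irg-5 in SAM_F3 against control_P0, which did not pass, ran from -0.498 without SAM_F3 2, where it passed as lower (adjusted p = 0.042), to 0.611 without SAM_F3 3. The ribosomal list in SAM_F3 against SAM_P0, which did not pass, ran from a median of -0.201 without SAM_F3 2 to 0.373 without SAM_F3 3, and was -0.201 without SAM_F3 2 and control_P0 3. The list then passed as lower (camera adjusted p = 0.00394 and 0.00491). In simulations with 59 to 71 genes changed at each fold, edgeR recovered at most 15.3% and DESeq2 at most 47.5% of the 2-fold changes, so many changes of that size would be missed where few genes change.

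For each of the 3 comparisons, 10 splits of the 6 libraries are too few for a share under 0.05. The real split, 1 of the 10, called 617, 2937 and 2869 genes, and the highest of the other splits called 0, 0 and 1.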

Other observations

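The tests below on SAM_F3 2, on moulting and yolk genes and on SAM_P0 genes in SAM_F3 were chosen after the results were seen, except the count of untreated F3 libraries. In SAM_F3 2, all 32 oocyte and eggshell genes lay lower than in the mean of SAM_F3 1 and 3, with a median shift of -1.42 ± 0.12 (log2, bootstrap SE), as did 27 of 30 core germline genes (-1.16 ± 0.09) and all 6 yolk genes. Sperm genes did not share this fall, with a median shift of 0.16 ± 0.07. Ribosomal protein (0.99 ± 0.05), muscle (0.97 ± 0.19), intestine (0.96 ± 0.18) and neuropeptide genes (0.95 ± 0.09) lay higher in SAM_F3 2.

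With the preset correlation, yolk genes were lower in SAM_P0 and in SAM_F3 than in the controls, and sperm genes lower in SAM_F3 (adjusted p = 0.423, 0.62 and 0.805 with an estimated correlation). The DAF-16-linked list was lower in each SAM_P0 library (-0.83, -0.66 and -0.91) than in any other library, and the noncoding RNA tts-1 took 0.016% to 0.02% of counts there, against 0.05% to 0.2% in the controls and 0.455% to 1.706% in SAM_F3. Tts-1, hsp-12.6, hsp-12.3, mtl-1 and hil-1 had lower means in SAM_P0 and higher means in SAM_F3 than in control_P0, although hsp-12.6 did not pass in SAM_P0 nor mtl-1 in SAM_F3.

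For the distance of SAM_F3 2 from its group, depth was argued against: SAM_F3 1, with a total only 1.3% above that of SAM_F3 2, correlated with SAM_F3 3 at 0.98, while the highest correlation of SAM_F3 2 with either was 0.919. A few abundant genes taking the counts would move all other genes alike, yet the intestine and oocyte shifts differed by 2.38 ± 0.22. A lower share of germline RNA as the whole cause would raise somatic lists alike. Neuron, muscle and intestine shifts differed by at most 0.45 ± 0.36. Muscle genes shifted by 0.72 ± 0.21 more than moulting genes (0.25 ± 0.10, with collagens at 0.59 ± 0.05), the largest gap among 6 somatic lists. The SE measures the spread over genes and not between libraries, so this gap cannot decide. A lower share, alone or together with changes in the somatic genes, stays open. No group of the design separates SAM_F3 2 from SAM_F3 1 and 3, so beyond this share no biological explanation was tested.

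For higher cuticle and moulting genes with lower yolk and eggshell genes in SAM_P0, scaling as the whole cause was argued against. Scaling by 1 factor per library cannot change the gap between collagen and yolk medians. By limma the gap was 2.22, and still 2.1 ± 0.16 (SE over genes, not between libraries) after quantile normalization, which can move abundant and scarce genes apart. Collection at an earlier stage may explain it and stays open: along the 268 genes of these lists, the difference of control_P0 3 from controls 1 and 2 correlated with that of SAM_P0 from the controls at r = 0.107 ± 0.078 (across genes, which are not independent), no more than the 0.108 over all genes tested, and sperm genes differed by 0.13 ± 0.18. Stage and SAM treatment cannot be told apart here, because the labels give only 1 stage and each group was 1 treatment. SAM treatment itself stays among the open explanations, as untested.

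For the genes of SAM_P0 in SAM_F3, the tables argued against none of the explanations. Of the 237 falls, 211 passed as higher in SAM_F3 than in SAM_P0, but they were chosen as low in the same 3 SAM_P0 libraries, so chance values of these libraries may contribute and cannot be told apart from an effect that ended. For the rises, of which 81.8% lay higher in SAM_F3 than in control_P0, chance values of the shared control libraries may contribute and cannot be told apart, because the 3 controls cannot be split. Generation or batch of the SAM_F3 worms stays open as well, with 0 untreated F3 libraries. A lasting effect of SAM on descendants was not tested by this design.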
